A study of Heterocephalus glaber with 3 samples.

How the data were processed

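Single-cell RNA sequencing was measured in lung tumours of 3 naked mole-rats (Heterocephalus glaber), 1 library per animal, which the labels place in 1 group. Per the labels, an adenovirus carrying CRISPR reagents gave edits that include the Eml4-Alk inversion and loss of Rb. Lungs were collected 15 weeks after infection, and tumours were separated by hand from normal tissue before dissociation and droplet capture with 10x Genomics 3' chemistry. The labels number the animals as replicates 1 to 3 and name no untreated animal, so no comparison between groups of animals was made, and all comparisons were between cell classes of the same animals.

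The deposited matrices hold raw UMI counts per gene and cell barcode, not normalized, 1 file per animal, per the file headers and the values. The file headers name Cell Ranger 7.1.0, whereas the submitters' processing notes name Cell Ranger 8.0.0. The genome build and annotation release are not given in the sources used here, and no genome was used. The feature list has 23189 entries, of which 11611 carry an identifier and no symbol. Features without a symbol held 37.8%, 36.8% and 37.2% of the counts in replicates 1, 2 and 3, entered the clustering and the gene tests, and were not named. None of the identifiers matched the reference table (0), so symbols were taken as the files give them. Of 246 members of 20 gene lists 169 were measured, and of 167 cell type markers 108, and EML4 was not analysed here. The 3 libraries shared 24, 21 and 31 barcodes in pairs, with 0 of equal UMI total, and were counted as 3 samples.

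The matrices held 9500, 10000 and 10000 barcodes with 76093932, 86575320 and 91949365 UMIs in replicates 1, 2 and 3. The median UMIs per barcode were 4363, 4822 and 6569, and the lowest totals 1298, 1150 and 2174, so the barcodes had been limited before deposit in a way the sources used here do not give. Cells were kept with at least 1000 UMIs, at least 500 genes and under 20% of counts in 13 mitochondrial genes. The mitochondrial limit applied to 1373, 949 and 2027 barcodes. Scrublet in scanpy 1.11.5 marked 5 of the 25044 passing cells with its automatic threshold, which counts as not having worked, so the 464 cells with a score of at least 0.2 were removed instead. The analysis kept 7927, 8883 and 7770 cells, 24580 in all.

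Counts were scaled to 10000 per cell and log-transformed. Clustering used 2000 variable genes without the members of the gene lists, 30 principal components, 20 neighbours and Leiden resolution 1, with no integration of animals (leidenalg 0.10.2, igraph 0.11.9). It gave 35 clusters. A cluster was called X-like from markers fixed before the data were examined, where at least 3 of them were detected in at least 10% of its cells and their mean log2 level lay at least 1 above the median cluster. It stayed unnamed where another lineage also passed at 50% or more of its score or scored higher, where another lineage or class had more markers among its 10 leading genes, or where at least 2 bone or osteoclast genes (such as DMP1, IBSP, ATP6V0D2 and TNFRSF11A) were among its 15 leading genes. This left 10 clusters unnamed. Type names were joined into classes: epithelial types, alveolar and other macrophages with monocytes, T with NK cells, and fibroblasts with mural cells.

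Several choices were made after the data had been seen. These are the Scrublet score of 0.2, the naming rule (revised 4 times while clusters were inspected), the threshold of 5 CPM for clusters called Alk-high, and both comparisons that use Alk-high clusters. Alk was removed from those comparisons after a first fit had included it. The last revision of the naming rule left clusters 7 and 15 unnamed. Both scored as monocyte or macrophage-like, but MMP8, a neutrophil marker, was among the leading genes of cluster 7, and FLT3 and FCER1A, dendritic and mast cell markers, were among those of cluster 15. The planned comparison of epithelial-like cells with and without an Alk UMI was not run, because 6, 6 and 35 such cells had an Alk UMI and a minimum of 20 had been set. It was replaced by the same comparison within the Alk-high clusters.

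For each comparison raw counts were summed per animal and class, giving 6 summed libraries. Cells with more UMIs thus weigh more in these sums. Genes were tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr, animal as block, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3. The animal was the block because both classes come from the same animal. The classes rest on clusters drawn from the same counts, so genes that formed the clusters were then tested between them. The p-values between classes are therefore not calibrated. Leaving list members out of the clustering does not remove other genes that vary with them. Gene lists with at least 3 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with fry, adjusted over the lists. The alternative with an estimated correlation had 2 residual degrees of freedom to estimate it, so a call lost there does not show an unchanged list. DESeq2 1.42.0 gave the alternative test. Up to 30 list members per class comparison were named by fold among those past the threshold with the same sign in all 3 animals; Alk and RB1 were named in every comparison of classes where tested. A further planned gene and the 2 lists that rest on it are not reported here, but counts of genes and lists past the threshold include them. In the Alk UMI comparison fewer than 5 genes passed, so the 6 highest and 6 lowest by p with a mean of at least 20 CPM were named. Members cited for single lists were taken from all measured members. Cells with and without an Alk UMI were matched by 10 equal classes of total UMIs and by cluster (seed 1).

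Cycling cells had at least 2 UMIs over 11 measured G2/M genes after thinning each cell to 1000 UMIs. Differences over 3 animals were tested by exact two-sided sign flips, whose smallest possible p is 0.25. Shares carry exact Clopper-Pearson intervals and CPM values exact Poisson intervals, both at 95% and for counting error only, and a count of 0 is read as allowing up to 3 counts. Spread over animals is given as SD, and the error of a fitted log2 fold change as SE.

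The edgeR step was tested on simulated counts with 200 changed genes per comparison. It recovered 87.6% of 4-fold and 39% of 2-fold changes among 14940 genes for epithelial-like cells, 100% and 69.7% among 14481 for monocyte or macrophage-like cells, and 92.9% and 55.6% among 14427 for T-like cells. For both Alk-high comparisons it recovered 100% and 65.7%, among 11150 genes for fibroblast-like cells and 10972 for cells with an Alk UMI. False calls made up 2.65% to 4.68% of calls. The simulated changes were balanced up and down at a fixed dispersion of 0.03. The comparisons of classes called far more genes, such as 4078 higher and 5020 lower in T-like cells. False calls under so wide a change were not simulated. The first version of the simulation was faulty, and the real fits had been seen before it was corrected.

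The alternatives fixed before the data were examined were UMI minimums of 500 and 2000, a mitochondrial limit of 10%, no doublet removal, resolutions of 0.5 and 2, list genes kept in clustering, DESeq2 size factors, the DESeq2 Wald test, no filter on low counts, no replicate block, an estimated correlation in camera, other thinning and each animal left out in turn. Alternatives added after seeing the data were doublets at the expected rate of 0.8% per 1000 barcodes, a common minimum of 2174 UMIs, an Alk-high threshold of 10 CPM, matching on UMIs only, fibroblast-like cells matched on UMIs, clusters 7 and 15 joined to the macrophage class, unnamed clusters 20 and 26, with a basal cell marker among their 10 leading genes, joined to the epithelial class, and all alternatives of both Alk-high comparisons. Figures were drawn with matplotlib 3.10.9.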

Results

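Lung tumours of 3 naked mole-rats with edits that include the Eml4-Alk inversion and loss of Rb were profiled by single-cell RNA sequencing 15 weeks after viral infection. The 3 animals form 1 group, with 76093932, 86575320 and 91949365 UMIs in replicates 1, 2 and 3, and 7927, 8883 and 7770 cells were kept. The labels describe a lung cancer model, and the comparisons ask which cells of the tumours express Alk and how cell classes of the same tumour differ.

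The tumours were rich in immune cells. Monocyte or macrophage-like cells made up 24.1% ± 3.28 (SD, n = 3) of kept cells, T-like cells 21.3% ± 6.03, plasma-like cells 10.2% ± 6.24 and fibroblast or mural-like cells 10.7% ± 2.43. Neutrophil-like cells made up 5.78% ± 3.39 and B-like cells 5.23% ± 3.81, but 1.77% and 2.83% with a minimum of 2000 UMIs and 1.72% and 2.35% with a common UMI minimum. Dendritic-like cells made up 3.76% ± 1.06 and endothelial-like cells 0.783% ± 0.303. Epithelial-like cells, the class that lines airways and alveoli, were a small part at 2.64% ± 1.41, with 190, 122 and 323 cells in replicates 1, 2 and 3. They comprised alveolar type 2-like cells (47, 83 and 112), ciliated cells (61, 25 and 53) and a general epithelial-like cluster led by SCGB3A2, Krt8 and EPCAM (82, 14 and 158). Unnamed clusters 20 and 26, with the basal cell marker KRT14 among their leading genes, were counted with all other cells, and joining them gave a share of 4.52% and 305, 391 and 412 cells. Cluster 20 was also led by TAGLN, IGF2, ACTA2 and MMP3, leading genes of fibroblast-like cluster 6, so the joined class may hold fibroblast-like cells. Unnamed clusters held 9.50%, 11.9% and 25.4% of the cells of replicates 1, 2 and 3. Among them clusters 7 and 15, which scored as macrophage-like but were kept out of that class by a rule set after they were seen, held 2.81%, 1.01% and 13.3%, and 2.04%, 1.10% and 7.05%. No mast or basophil-like cluster was named (0 cells, which does not exclude single cells). All intervals and floors cover counting error only, and the lowest UMI total among the barcodes was 2174 in replicate 3 against 1298 and 1150 in the others.

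**Figure D1:**
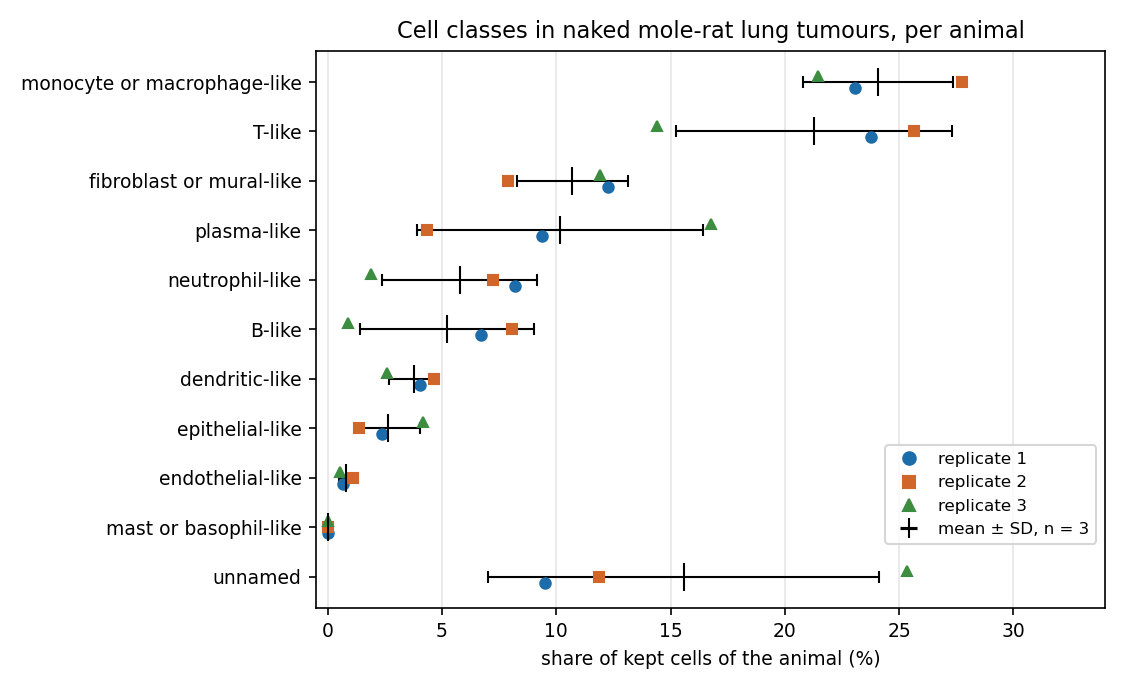
Share of kept cells in each class (x axis, percent), with a point for each of the 3 animals and the mean ± SD. Monocyte or macrophage-like and T-like cells are the leading classes with means of 24.1% and 21.3%, and epithelial-like cells lie between 1.37% and 4.16%.

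Alk, the receptor tyrosine kinase gene placed under the Eml4 promoter by the inversion, was highest in 5 of the 35 clusters. Cluster 26, led by SERPINE2, KRT14 and SPINK5, had 63.6 CPM (95% Poisson interval 57.4 to 70.3). Of its 201 cells 198 were from replicate 2, at 64.6 CPM. Cluster 22, led by the bone matrix genes SPP1, DMP1 and IBSP, had 48.2 CPM (43.0 to 53.9), with 40.6, 48.7 and 44.8 CPM in replicates 1, 2 and 3. Cluster 21, general epithelial-like, had 15.4 CPM, with 5.56, 34.3 and 18.3 CPM in replicates 1, 2 and 3. Cluster 6, fibroblast-like and led by MMP3, IGF2 and COL1A1, had 14.4 CPM, with 11.1, 19.7 and 16.7 CPM. Cluster 20, unnamed, had 5.44 CPM from 8 Alk UMIs (2.35 to 10.7), which overlaps clusters not chosen, such as cluster 4 (1.87 to 4.98), and it was not chosen when replicate 2 was left out. Alveolar type 2-like cells gave 0 Alk UMIs in 242 cells, which allows up to 1.80 CPM at 3 counts.

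These 5 clusters, called Alk-high below at a threshold of 5 CPM set after their values were seen, held 9.49% ± 0.937 (SD, n = 3) of the cells. Their Alk level was 24.1 ± 17.8 CPM against 0.955 ± 0.647 CPM in all other cells, a ratio of 25.8 ± 9.95 that was above 1 in 3 of 3 animals. By replicate the levels were 10.8, 44.3 and 17.1 CPM against 0.691, 1.69 and 0.482 CPM, and without replicate 2 the means were 14.0 and 0.587 CPM. When the clusters were chosen from the other animals, the ratio in the animal left out was 15.7, 26.0 and 35.5 for replicates 1, 2 and 3. An Alk UMI was seen in 24.1% of cluster 6 cells (median 19853 UMIs) and in 0.539% of plasma-like cluster 2 cells (median 13577 UMIs), which should lack the gene. Clusters 22 and 26 came mainly from replicate 2, with 11, 224 and 10 cells and 2, 198 and 1 cells in replicates 1, 2 and 3. The 3' counts do not tell the fusion transcript from native Alk, and counts of RB1 do not show whether a copy was edited.

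**Figure D2:**
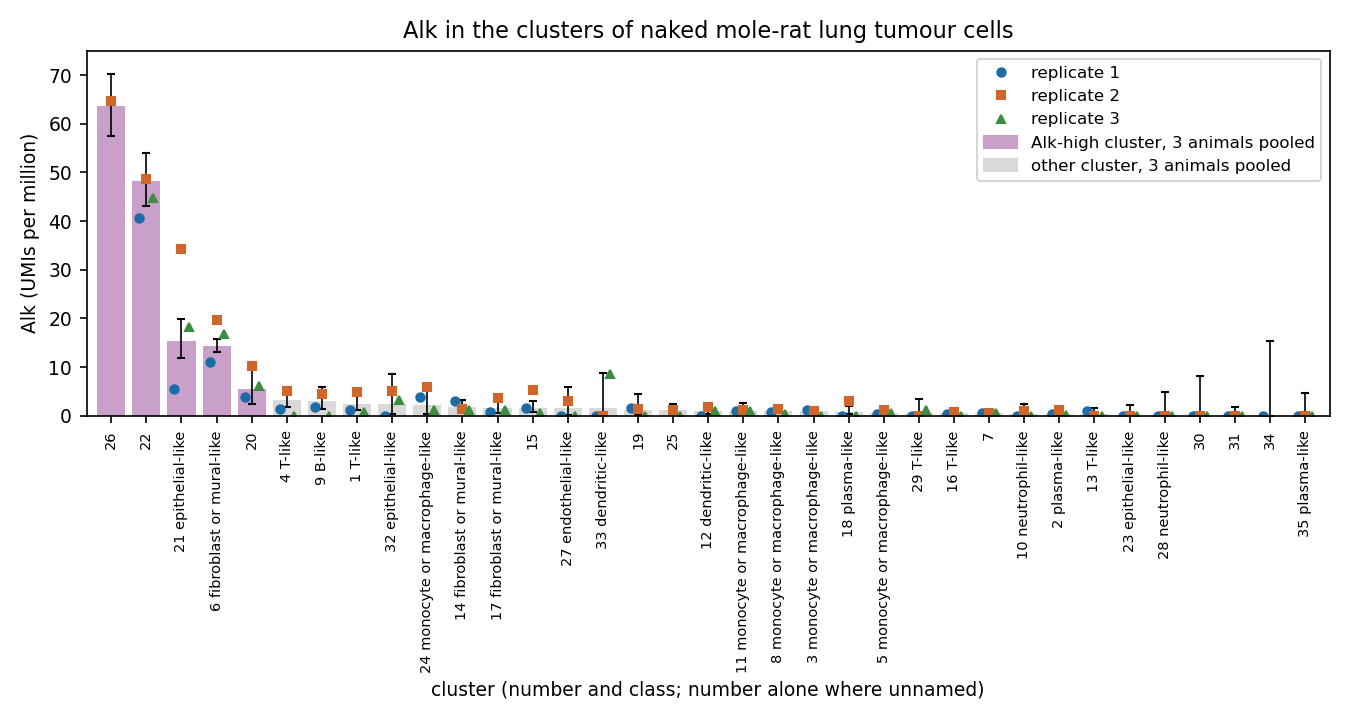
Alk in CPM (y axis) for each of 35 clusters (x axis). Bars pool the 3 animals with exact 95% Poisson intervals, and points give each animal with at least 5 cells in the cluster. Clusters 26, 22, 21, 6 and 20 stand highest, at 63.6, 48.2, 15.4, 14.4 and 5.44.

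Alk and RB1 were compared between epithelial-like cells and all other cells. Alk was at 3.59, 10.5 and 13.1 CPM in epithelial-like cells and 3.33, 11.2 and 2.74 CPM in all others in replicates 1, 2 and 3. The fitted difference was 0.74 ± 0.43 (log2 ± SE, n = 3), higher in 2 of 3 animals and not past the threshold in edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.21), and it was −0.17 without replicate 3. Within the class cluster 21 held 61 Alk UMIs, against 0 in alveolar type 2-like and 2 in ciliated cells. Cluster 21 numbered 82, 14 and 158 cells in replicates 1, 2 and 3. The other cells of replicate 2 held cluster 26, with Alk at 64.6 CPM. With clusters 20 and 26 joined to the class Alk was at 3.56, 55.2 and 12.7 CPM against 3.33, 6.87 and 2.69 CPM, a fitted difference of 1.84 that did not pass (edgeR adjusted p = 0.062). RB1, the brake on entry into the cell cycle, was lower by a log2 fold change of −0.67 ± 0.22 (edgeR, Benjamini-Hochberg adjusted p = 0.037, lower in 2 of 3 animals). The call of RB1 was lost without replicate 1 (edgeR adjusted p = 0.18), without replicate 2 (0.099), in DESeq2 (0.065) and with these clusters joined (0.076).

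Genes of the cell cycle and mesenchymal lists were lower in epithelial-like cells than in the rest of the tumour, while their share of cycling cells at equal depth was lower in 2 of 3 animals (exact two-sided sign-flip test, p = 0.5, smallest possible 0.25). All 11 measured G2/M genes fell (median log2 fold change −1.36), among them UBE2C (−1.88 ± 0.14), TOP2A (−1.55 ± 0.15) and CDK1 (−1.36 ± 0.20), which drive chromosome separation and mitotic entry (camera adjusted p = 1.5e-05, and adjusted p = 0.53 with an estimated correlation). Of 14 G1/S and E2F targets 11 fell, 12 when adjusted over the list alone, such as CDC6 (−1.90 ± 0.42) and MCM3 (−1.01 ± 0.15), which license DNA replication. The list passed (camera adjusted p = 0.0032, and adjusted p = 0.53 with an estimated correlation; adjusted p = 0.051 without replicate 2). Of 7 mesenchymal transition genes 6 fell and 7 adjusted over the list alone, including the intermediate filament gene Vim (−2.48 ± 0.19) and the repressors of epithelial genes ZEB2 (−3.50 ± 0.22) and ZEB1 (−2.35 ± 0.29). The list passed (camera adjusted p = 1.2e-05, and adjusted p = 0.53 with an estimated correlation). Each named gene was lower in 3 of 3 animals. The class held alveolar type 2-like and ciliated cells, with 0 and 2 Alk UMIs. Alk-high clusters 6, 20, 22 and 26 stood on the other side, with fibroblast-like and macrophage-like cells. The comparison therefore does not set tumour epithelium apart from normal epithelium. With clusters 20 and 26 joined to the class G2/M and mesenchymal transition passed (camera adjusted p = 0.029 and 0.021) and G1/S did not (0.13). The medians were then −0.87, −1.01 and −0.48, and 2 of 11, 3 of 7 and 2 of 14 genes of these lists passed. TOP2A at −0.93, CDK1 at −0.41, CDC6 at −0.52, MCM3 at −0.25, Vim at −0.98 and ZEB1 at −1.01 did not (edgeR adjusted p from 0.056 to 0.70).

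Of the immune lists, myeloid cytokines and T cell inhibitory and regulatory genes were lower in epithelial-like cells as well. Of 8 myeloid cytokine genes 6 fell, including TNF (−3.16 ± 0.21) and IL1B (−2.88 ± 0.12), the inflammatory cytokines of macrophages, with 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 9.0e-04, and adjusted p = 0.53 with an estimated correlation). Of 10 T cell inhibitory and regulatory genes 7 fell and 1 rose, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.012, and adjusted p = 0.64 with an estimated correlation). CTLA4 (−2.77 ± 0.41) and LAG3 (−2.65 ± 0.37), which restrain T cells, were among them. On the other side of the comparison stood the T-like and monocyte or macrophage-like cells that express such genes, 21.3% and 24.1% of all kept cells. These are shares of cells and not of the summed counts. T-like cluster 1, for 1, had a median of 2221 UMIs per cell, against 19853 in cluster 6.

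Genes higher in epithelial-like cells in 3 of 3 animals belonged to several lists that did not pass as a whole. SOX9 (2.41 ± 0.31), SOX2 (1.74 ± 0.29) and ITGA2 (1.96 ± 0.18), lung progenitor transcription factors and a collagen-binding integrin, rose in the lung tumour dedifferentiation list, where 3 of 7 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.48). ETV4 (1.22 ± 0.31), EPHA2 (1.07 ± 0.22) and CCND1 (0.86 ± 0.22), targets of MAPK signalling, rose among 7 MAPK output genes, of which 1 fell (camera adjusted p = 0.50). SREBF1 (1.65 ± 0.16), the activator of fatty acid synthesis, SQLE, ACACA and FASN rose among 7 lipid and sterol genes (1 lower adjusted over the list alone; camera adjusted p = 0.22). ANKRD37 (2.92 ± 0.22), a hypoxia-induced gene, GCLM (2.81 ± 0.27), a subunit of the enzyme that starts glutathione synthesis, FABP5 (2.69 ± 0.14), a fatty acid carrier, and NECTIN2 (1.77 ± 0.17), a ligand of TIGIT and CD226, also rose. HAS1, a hyaluronan synthase, had 0 UMIs in epithelial-like cells, at least 2.72-fold lower than in all others against a floor of 3 counts over the 3 animals, and with it at that bound the median of the hyaluronan list was −1.44 (camera adjusted p = 0.086 as fitted). With clusters 20 and 26 joined to the class FASN at 0.69, ETV4 at 1.01, ITGA2 at 1.22, CCND1 at 0.51, EPHA2 at 0.37 and HAS1 at −0.61 did not pass (edgeR adjusted p from 0.083 to 0.74).

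The other lists did not pass with camera in epithelial-like cells. Of MHC class II genes 4 of 7 fell (adjusted p = 0.089), of MHC class I processing genes 2 of 8 fell (0.47) and of interferon response genes 3 of 10 fell (0.30). Of hypoxia and glycolysis genes 3 of 12 rose and 4 fell (0.50), of hyaluronan genes 1 of 9 rose and 7 fell, and of NRF2 antioxidant genes 1 of 8 rose and 5 fell (0.19). Of checkpoint ligands 1 of 4 rose and 2 fell (0.48), of cytotoxic effectors 2 of 4 fell (0.12), of tumour macrophage genes 1 of 7 rose and 4 fell (0.056) and of dissociation stress genes 4 of 7 fell (0.070). Adjusted over the list alone 3 checkpoint ligands, 3 cytotoxic effectors, 5 tumour macrophage, 5 dissociation stress and 5 hypoxia and glycolysis genes were lower. With fry the hyaluronan and tumour macrophage lists passed as lower (fry adjusted p = 0.027 for each). In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 2831 genes higher and 2905 lower among 14663, and 110 of 164 list genes. With clusters 20 and 26 joined it called 1699 and 1523, and 71 list genes, and 9 lists passed, with MHC class I and II, interferon response, cytotoxic effectors and tumour macrophage lower as well (camera adjusted p from 8.1e-04 to 0.043). Here and in the later comparisons of classes, such counts follow in part from the clustering, which used the same cells.

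The fibroblast-like cells of cluster 6 with Alk were compared with the other fibroblast-like cells, a comparison chosen after Alk had been seen there. CDKN1A, a cell cycle inhibitor, fell by 1.96 ± 0.12 on the log2 scale (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, lower in 3 of 3 animals). RB1 was at −0.50 ± 0.19 and did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.059), but passed with a minimum of 2000 UMIs (adjusted p = 0.044), a mitochondrial limit of 10% (0.049), no doublet removal (0.038) and list genes kept in clustering (0.045). Of 7 lung tumour dedifferentiation genes 5 rose. These were GKN2, a secreted stomach protein, at 80.4, 124 and 15.8 CPM against 0.80, 0.66 and 0 in replicates 1, 2 and 3, and SOX2 (3.29 ± 0.32), ITGA2 (3.20 ± 0.20), HMGA2 (3.11 ± 0.35), a chromatin protein of embryonic tissue, and Clu (0.88 ± 0.11). The list passed (camera adjusted p = 3.8e-05, and adjusted p = 0.54 with an estimated correlation). ETV4 (3.10 ± 0.27) and CSF2 (5.14 ± 0.39), which encodes the cytokine GM-CSF, also rose in 3 of 3 animals.

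All 11 G2/M genes (median 2.51, such as TOP2A at 2.51 ± 0.29 and TPX2 at 2.35 ± 0.14) and all 12 G1/S and E2F targets (median 1.52) rose in these cells (camera adjusted p = 1.5e-08 and 9.2e-05, and adjusted p = 0.54 for both with an estimated correlation). The cells were deeper, at medians of 21797, 20246 and 17285 UMIs against 5819, 5520 and 4948 in replicates 1, 2 and 3, and with cells matched on UMIs both cycle lists lost their call (camera adjusted p = 0.31 and 0.32). TOP2A was then at 0.60, CDK1 at 0.55, UBE2C at −0.054 and NUSAP1 at −0.096, none past the threshold, while CENPF (1.36), BIRC5 (1.16) and TPX2 (0.99) passed (edgeR adjusted p = 0.016, 0.013 and 0.024). Hypoxia and glycolysis genes rose in 8 of 12, including the glycolytic enzymes Eno1 (1.41 ± 0.11) and PGK1 (1.30 ± 0.11) (camera adjusted p = 0.017, and adjusted p = 0.54 with an estimated correlation; 5.2e-05 when matched on UMIs and 0.056 with no replicate block). The dedifferentiation list (0.0034), HMGA2 at 3.95 and ETV4 at 2.83 also passed when matched on UMIs. GKN2, SOX2 and CSF2 had too few counts to be tested there.

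The MHC class I processing and interferon response lists were lower in the Alk-high fibroblast-like cells, but did not pass with cells matched on UMIs. CCL2, a chemokine that attracts monocytes, fell by 3.61 ± 0.24 on the log2 scale and CD274, which encodes the checkpoint ligand PD-L1, by 2.98 ± 0.20, each lower in 3 of 3 animals. Of 8 MHC class I processing genes 7 fell, such as TAPBP (−1.39 ± 0.14) and TAP1 (−0.71 ± 0.11), both of the peptide-loading complex. Of 10 interferon response genes 6 fell, 7 adjusted over the list alone, such as IFIT2 (−2.04 ± 0.18; adjusted p = 0.17 with no replicate block). Both lists passed (camera adjusted p = 0.047 for each, and adjusted p = 0.54 and 0.62 with an estimated correlation). With fry MHC class I passed (fry adjusted p = 0.019) and interferon response did not (0.069). The dissociation stress genes, which answer to tissue handling, all fell (7 of 7, such as Fos at −1.55 ± 0.14; camera adjusted p = 6.0e-06, and adjusted p = 0.54 with an estimated correlation). With cells matched on UMIs the MHC class I and interferon lists did not pass (camera adjusted p = 0.11 and 0.25), nor did MHC class I without replicates 1 or 3 (0.073 and 0.089), interferon without replicate 2 (0.074) or with a minimum of 2000 UMIs (0.071). Neither passed at resolution 2 (0.054 each) or with no replicate block (0.34 and 0.54). With cells matched on UMIs dissociation stress passed (camera adjusted p = 2.9e-06), as did CCL2 at −3.72, CD274 at −2.19 and IFIT2 at −1.43 (edgeR adjusted p = 8.1e-06, 5.6e-05 and 0.011). Such matching draws on the shallower Alk-high cells and called fewer genes in all. The lost calls of the MHC class I and interferon lists therefore do not show unchanged lists.

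The remaining lists did not pass with camera in fibroblast-like cells (camera adjusted p from 0.13 to 0.92). With fry MAPK output, checkpoint ligands, tumour macrophage and lipid and sterol synthesis passed (fry adjusted p = 0.020, 0.020, 0.019 and 0.034). Of lipid and sterol genes 4 of 7 rose, of NRF2 antioxidant genes 4 of 8 rose, of MAPK output genes 3 of 7 rose (with 2 lower adjusted over the list alone), and of myeloid cytokines 2 of 8 rose and 5 fell. Of mesenchymal transition genes 2 of 7 rose and 4 fell, of MHC class II genes 1 of 7 rose and 4 fell, of checkpoint ligands 1 of 3 rose and 2 fell, and of T cell inhibitory genes 3 of 6 fell. Of hyaluronan genes 1 of 7 rose and 2 fell (1 adjusted over the list alone), and of tumour macrophage genes 2 of 7 rose and 3 fell, with a median of −0.07, a mean of 0.18 and an upward test. GZMB, a cytotoxic granule protease, rose as 1 of 2 cytotoxic effectors measured. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 2641 genes higher and 2560 lower among 11126, against 1035 and 1254 with cells matched on UMIs, and 111 of 151 list genes against 74.

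**Figure D3:**
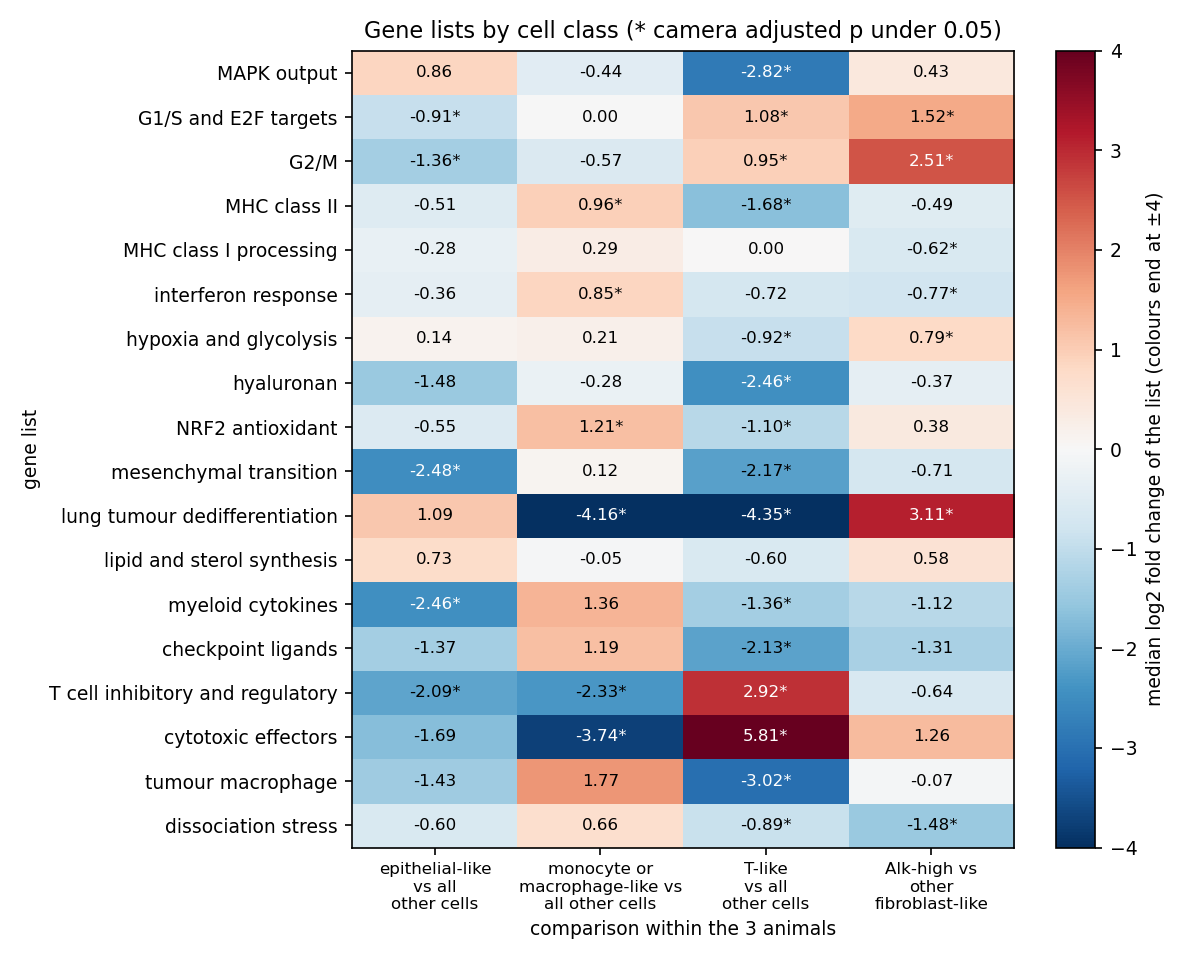
Median log2 fold change of each of 18 gene lists (y axis) in 4 comparisons within the 3 animals (x axis), as colour and number, with a star for a camera adjusted p under 0.05. No list passed with an estimated correlation, which rests on 2 residual degrees of freedom. In fibroblast-like cells the 2 cycle lists, MHC class I and interferon lists did not pass with cells matched on UMIs. That matching draws on the shallower Alk-high cells, so a call lost there does not show an unchanged list.

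No gene passed the test between Alk-high cells with an Alk UMI and matched cells of the same clusters without one, with 134, 192 and 152 cells per side in replicates 1, 2 and 3. edgeR's quasi-likelihood test called 0 of 10790 genes, with 787 at an unadjusted p under 0.05, and DESeq2 called TUBA1A alone, 1 gene (adjusted p = 0.034). Among the 12 genes named as not passing, TUBA1A, an alpha tubulin, was at −0.52 ± 0.07 (edgeR, Benjamini-Hochberg adjusted p = 0.37), lower in 3 of 3 animals. F5, a clotting factor, was at 0.69 ± 0.14 and C4BPA, a complement inhibitor, at 0.50 ± 0.09 (adjusted p = 0.56 and 0.55), both higher in 3 of 3 animals. F5 and C4BPA were higher along with ALPL, REL, MSR1 and KIF3A, and GPRC5A, WIPI1, DCN, TAGLN and PLAUR were lower along with TUBA1A, at adjusted p of up to 0.63. None of 18 lists passed (0 with camera, whose adjusted p was at least 0.145), and 0 of 149 list genes did. Under some alternatives lists did pass, among them interferon response (10 alternatives), hypoxia and glycolysis (7) and tumour macrophage (5) as lower, and lipid and sterol synthesis (6) and G2/M (4) as higher. Adjusted over the list alone 1 dedifferentiation, 2 tumour macrophage and 1 dissociation stress gene were lower. The G1/S, MHC class II, hypoxia, NRF2 and myeloid cytokine lists had a median, mean and test of differing sign. A cell without an Alk UMI can still express Alk, and 22 genes and 10 lists were called without matching, and 37 genes, TUBA1A, F5, GPRC5A, DCN and TAGLN among them, with no filter on low counts. Without replicates 1, 2 and 3 it was 13, 5 and 21 genes, and ALPL (adjusted p = 0.021) and TAGLN (0.0056) passed without replicate 3.

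Summed as a class, monocyte or macrophage-like cells were higher than all other cells in antigen presentation, interferon response and antioxidant genes. Of 7 MHC class II genes 6 rose, 7 adjusted over the list alone, including HLA-DRA (1.33 ± 0.25) and CD74 (0.92 ± 0.23), both of the pathway that presents peptides to helper T cells (camera adjusted p = 0.015, and adjusted p = 0.91 with an estimated correlation). Of 10 interferon response genes 9 rose, such as OAS1 (2.19 ± 0.16) and IFIT3 (2.03 ± 0.11), which act against viral RNA (camera adjusted p = 1.1e-04, and adjusted p = 0.63 with an estimated correlation; adjusted p = 0.17 with no replicate block). Of 8 NRF2 antioxidant genes 7 rose and 1 fell, with HMOX1 (2.75 ± 0.17), which breaks down haem, and SRXN1 (2.85 ± 0.10) in front (camera adjusted p = 1.5e-04, and adjusted p = 0.50 with an estimated correlation). With fry the NRF2 list passed (fry adjusted p = 0.011), but MHC class II and interferon response did not (0.099 and 0.056). All values are log2 fold change ± SE, and each named gene was higher in 3 of 3 animals. OAS1 and IFIT3 were leading genes of cluster 3, which held 912, 1016 and 60 cells in replicates 1, 2 and 3. HMOX1 was a leading gene of clusters 5 and 24, with 334, 339 and 900, and 92, 53 and 93 cells. Whether these genes were higher in every cluster of the class was not tested.

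GPNMB (4.21 ± 0.26), a glycoprotein of lipid-laden macrophages, CTSD (3.36 ± 0.17), a lysosomal protease, LPL (2.68 ± 0.36), TNF (2.55 ± 0.33) and the costimulatory ligand CD86 (2.38 ± 0.26) rose as well. GPNMB, CTSD and LPL were leading genes of cluster 5. Of tumour macrophage genes 4 of 7 rose and 2 fell (camera adjusted p = 0.060), and of myeloid cytokines 6 of 8 rose and 1 fell (0.058). Of checkpoint ligands 2 of 4 rose and 1 fell, or 3 and 1 adjusted over the list alone (0.73). With fry myeloid cytokines passed (fry adjusted p = 0.011), while tumour macrophage and checkpoint ligands did not (0.056 and 0.70). All 4 cytotoxic effectors fell (camera adjusted p = 8.8e-05), as did 6 of 7 dedifferentiation genes with PLAUR higher (camera adjusted p = 0.0014), and 8 of 10 T cell inhibitory genes with ENTPD1 higher (camera adjusted p = 0.0099), each with adjusted p = 0.50 with an estimated correlation. The T cell inhibitory list did not pass with clusters 7 and 15 joined to the class (camera adjusted p = 0.10). Alk fell by 2.99 ± 0.25 on the log2 scale and RB1 was at 0.05 ± 0.14 (−0.098 without replicate 1).

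The other lists did not pass in these cells (camera adjusted p from 0.186 to 0.983). Of hypoxia and glycolysis genes 5 of 12 rose and 3 fell, and of hyaluronan genes 2 of 9 rose and 3 fell (4 adjusted over the list alone). Of G2/M genes 3 of 11 fell (0 adjusted over the list alone). Of dissociation stress genes 3 of 7 rose, of MHC class I genes 2 of 8 rose (0 adjusted over the list alone) and of lipid and sterol genes 1 of 7 fell. Of MAPK output genes 2 of 7 rose and 3 fell (4 adjusted over the list alone), with a median of −0.44 and a mean of −0.32 against an upward test. Of G1/S targets 3 of 14 rose (2 adjusted over the list alone), with a median of −0.0029, a mean of 0.05 and an upward test. Of mesenchymal transition genes 3 of 7 rose and 2 fell, with a median of 0.12, a mean of −0.29 and a downward test. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3394 genes higher and 4109 lower among 14446, and 102 of 164 list genes. Without replicate 1 it called 1532 higher genes and 67 list genes, without replicate 2 2013 higher genes, and with no replicate block 2100.

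Cytotoxic genes and inhibitory genes were each higher in T-like cells than in all other cells. All 4 cytotoxic effectors rose (median 5.81), with IFNG (5.88 ± 0.38), the main T cell interferon, and the granzymes GZMK (5.87 ± 0.15) and GZMA (5.76 ± 0.18) (camera adjusted p = 2.1e-10, and adjusted p = 0.38 with an estimated correlation). Of 10 T cell inhibitory and regulatory genes 8 rose, including TIGIT (5.89 ± 0.41), CTLA4 (5.55 ± 0.31), PDCD1 (3.19 ± 0.12) and FOXP3 (5.51 ± 0.30), the factor of regulatory T cells, while LAYN and ENTPD1 fell. The list passed (camera adjusted p = 1.5e-05, and adjusted p = 0.38 with an estimated correlation). All 11 G2/M genes and 12 of 15 G1/S targets rose, such as TOP2A (1.47 ± 0.16) and Pcna (1.42 ± 0.12) (camera adjusted p = 9.8e-04 and 0.0042, and adjusted p = 0.49 for both with an estimated correlation). With fry G2/M passed (fry adjusted p = 0.047) and G1/S did not (0.064). Each named gene kept its direction in 3 of 3 animals, and values are log2 fold change ± SE. All other cells are mainly of other lineages, so a rise of T cell genes follows in part from the comparison itself. GZMA and GZMK were leading genes of cluster 4, and FOXP3 and CTLA4 of cluster 13. Whether single cells express both lists was not tested.

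Several further lists were lower in T-like cells. MAPK output, MHC class II and dedifferentiation genes fell in 7 of 7 each, such as CCND1 (−3.03 ± 0.12) and SOX2 (−4.35 ± 0.34). Tumour macrophage genes fell in 6 of 7 with FABP5 higher, myeloid cytokines in 6 of 8 and checkpoint ligands in 3 of 4, or 4 adjusted over the list alone. Hypoxia and glycolysis genes fell in 9 of 12 and rose in 2, hyaluronan genes fell in 7 of 9 and rose in 1, and NRF2 genes fell in 6 of 8 and rose in 2. Mesenchymal transition genes fell in 5 of 7 and rose in 1, and dissociation stress genes fell in 6 of 7. The camera adjusted p of these 11 lists ran from 1.5e-05 to 0.038, and with an estimated correlation adjusted p = 0.38 to 0.43. NRF2 and mesenchymal transition did not pass with no filter on low counts (camera adjusted p = 0.058 and 0.053), nor did dissociation stress with no replicate block (0.095).

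Of interferon response genes 7 of 10 fell in T-like cells, 8 adjusted over the list alone, and 1 rose, and the list did not pass (camera adjusted p = 0.052). Nor did MHC class I processing, where 3 of 8 rose and 1 fell (0.60), and lipid and sterol genes, where 5 of 7 fell (0.36). With fry interferon response and lipid and sterol synthesis passed as lower (fry adjusted p = 0.026 and 0.011). RB1 (0.98 ± 0.11) rose and Alk fell (−2.38 ± 0.24), each in 3 of 3 animals. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 4078 genes higher and 5020 lower among 14349, and 142 of 165 list genes.

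The share of cycling cells, by at least 2 UMIs over 11 G2/M genes at 1000 UMIs per cell, was 4.76% ± 2.90 (SD, n = 3) in epithelial-like cells, at 7.37%, 1.64% and 5.26% in replicates 1, 2 and 3. It was 6.84% ± 0.914 in all other cells, and the difference of −2.08 ± 3.80 percentage points was within the spread between animals (exact two-sided sign-flip test, p = 0.5, smallest possible 0.25). T-like cells were at 11.1% ± 3.56 and monocyte or macrophage-like cells at 4.79% ± 2.35. The latter share was 1.65% with the mitochondrial limit of 10%, 8.16% with a minimum of 2000 UMIs, 8.14% at resolution 2 and 8.23% with list genes kept in clustering. In Alk-high fibroblast-like cells the share was 10.0% ± 2.47 against 0.693% ± 0.360 in other fibroblast-like cells, higher in 3 of 3 animals by 9.33 ± 2.59 percentage points (exact two-sided sign-flip test, p = 0.25, the smallest possible). Without thinning these shares were 53.6% and 7.48%. UMIs from free RNA can enter these shares. With fibroblast-like cells matched on UMIs in place of thinning, the G2/M list did not pass (camera adjusted p = 0.31). Such matching draws on the shallower Alk-high cells, so this lost call does not show equal shares of cycling cells.

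**Figure D4:**
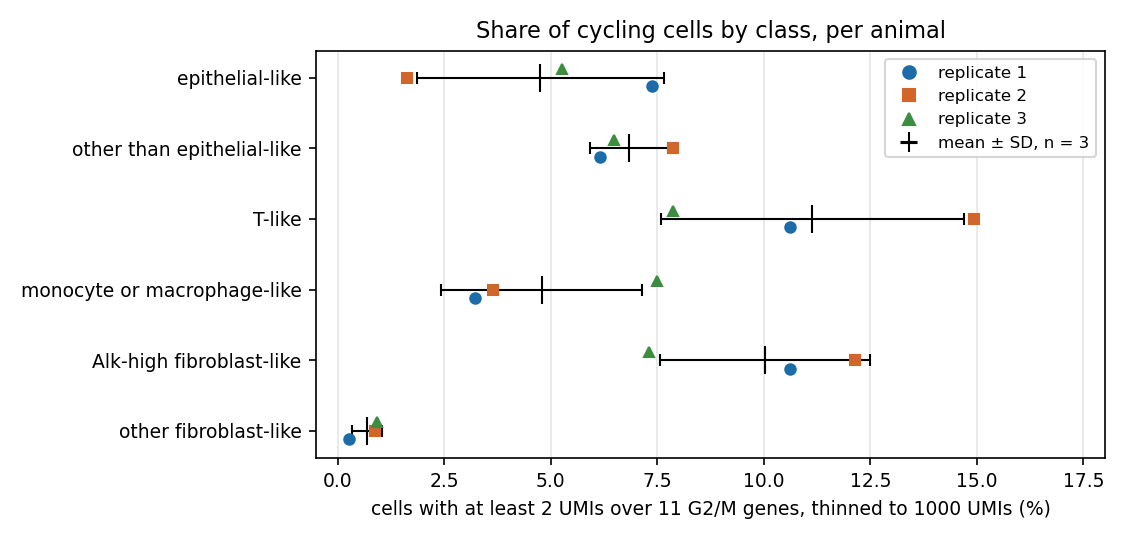
Share of cells with at least 2 UMIs over 11 G2/M genes after thinning to 1000 UMIs (x axis, percent), with a point for each of the 3 animals and the mean ± SD for 6 classes (y axis). Other fibroblast-like cells lie below 1% in each animal and Alk-high fibroblast-like cells between 7.32% and 12.1%.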

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

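The alternatives of both Alk-high comparisons, doublets at the expected rate, the common UMI minimum, the 10 CPM threshold, matching on UMIs and the joined myeloid or basal-led clusters were tests chosen after the results were seen. Of 2890 values of single genes and lists under the alternatives 2795 kept their direction and side of the threshold, 79 lost their call, 33 of them with an estimated correlation, 12 gained one and 4 turned. This tally covers Alk, RB1, the up to 30 members named by fold per class comparison, the genes named in the Alk UMI comparison and the lists that passed. Other cited genes, such as TOP2A and CDK1 in epithelial-like cells, are not in it, nor are their lost calls. The count of lists fell to 0 with an estimated correlation in each of the 4 comparisons of classes. That correlation was estimated with 2 residual degrees of freedom. Even the cytotoxic list of T-like cells, with 4 of 4 genes higher, did not pass there, so this loss cannot tell which lists are unchanged. With no replicate block 9 single calls of the tally were lost. These were GZMK, OAS1 and GZMA in epithelial-like cells, interferon response in macrophage-like cells, dissociation stress in T-like cells, and IFIT2, MHC class I, interferon response and hypoxia in fibroblast-like cells. It also gave 2100 higher genes in macrophage-like cells and 1592 higher genes and 4 lists in fibroblast-like cells, and changed no other call of the tally. Calls and shares rest on 3 animals, and depth limits rare transcripts such as Alk. Beyond what each alternative does to cells or genes by its construction, the cause was not tested. The UMI minimum of 500 kept the same 24580 cells, and the 10 CPM threshold the same fibroblast-like cells. Their values were thus kept by construction and add to the 2795. Most named genes were also chosen because they passed, so this tally is no measure of how firm the calls are. The comparison of epithelial-like cells by Alk UMI and its alternatives were not run.

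The macrophage-like share was 33.2% with the joined clusters, 28.0% with a minimum of 2000 UMIs, 32.2% at resolution 0.5 and 27.8% with the common UMI minimum. The neutrophil-like share was 1.77% with 2000 UMIs and 1.72% with the common minimum. At resolution 0.5 dendritic-like cells were at 5.04%, unnamed cells at 5.02% and mast or basophil-like cells at 0.155%, also at resolution 2. Alk-high clusters held 7.94% with a mitochondrial limit of 10%, 8.40% at resolution 2 and with list genes kept, 10.9% with the common minimum and 8.37% at 10 CPM.

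The cycling share, thinned to 2000 UMIs, was 11.6% in cells other than epithelial-like, 18.2% in T-like, 8.20% in macrophage-like, 13.9% in Alk-high and 1.81% in other fibroblast-like cells. With 1 UMI enough it was 12.6% in epithelial-like cells, and in the order above 17.0%, 21.5%, 14.9%, 22.1% and 8.16%. Not thinned it was 18.4%, 25.8%, 20.5%, 28.9%, 53.6% and 7.48%. With the common minimum it was 7.99% in cells other than epithelial-like and 14.9% in T-like cells. In macrophage-like cells it was 8.16% with 2000 UMIs, 1.65% with the mitochondrial limit of 10%, 8.14% at resolution 2 and 8.23% with list genes kept. In other fibroblast-like cells it was 1.49% with 2000 UMIs and 1.14% with no doublet removal.

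In epithelial-like cells Alk ranged from −0.17 to 1.19 and RB1 from −0.92 to −0.55 with 1 animal left out. RB1 was at −0.69 in DESeq2, not past the threshold. With the basal-led clusters 20 and 26 joined the epithelial-like share was 4.52%, RB1 at −0.68 did not pass, and 71 list genes, 9 lists, 1699 higher and 1523 lower genes did. In macrophage-like cells 67 to 133 list genes and 1532 to 4039 higher genes were called with 1 animal left out, RB1 was at −0.098 to 0.25, and 10 lists passed with the mitochondrial limit of 10%. With fibroblast-like cells matched on UMIs 4 lists, 1035 higher and 1254 lower genes passed, and UBE2C was at −0.054 and NUSAP1 at −0.096. RB1 there passed at −0.55 with 2000 UMIs and with no doublet removal, −0.60 with the mitochondrial limit of 10% and −0.54 with list genes kept.

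For cells with an Alk UMI the count of genes was 22 with no matching, 37 with no filter on low counts, 4 with 2000 UMIs and with no doublet removal, and 3 at resolution 0.5 and with doublets at the expected rate. It was 2 with the common minimum, 1 at resolution 2, with list genes kept, at 10 CPM and in DESeq2, and 5 to 21 with 1 animal left out. List genes numbered 2 with no matching and 0 to 1 with 1 animal left out. Lists numbered 10 with no matching, 6 with doublets at the expected rate and 5 matched on UMIs only. They numbered 4 with 2000 UMIs, at resolution 0.5, with list genes kept and at 10 CPM, 3 with at least 2 Alk UMIs, 1 with the mitochondrial limit of 10% and with no doublet removal, and 0 to 2 with 1 animal left out.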

Other observations

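The tests of technical explanations and of other splits given here were all chosen after the results had been seen, and the clusters described first were picked for their leading genes after these were seen. Cluster 22 was led by SPP1, DMP1 and IBSP, genes of mineralised bone matrix, with PTH1R, the parathyroid hormone receptor of bone cells, and it held 11, 224 and 10 cells in replicates 1, 2 and 3. SPP1 stood at 3099, 77002 and 779 CPM in the cluster 22 cells of these replicates. Cluster 25 was led by ATP6V0D2, MMP9 and TNFRSF11A, genes of osteoclasts, the cells that resorb bone, and it held 2, 194 and 8 cells. In replicate 2 its levels were 2795 CPM for ATP6V0D2 and 6555 CPM for MMP9.

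Cluster 31 was led by MSLN, TFPI2 and PRG4, which encode mesothelin, a serine protease inhibitor and lubricin, and it held 7, 34 and 118 cells in replicates 1, 2 and 3. HAS1, a hyaluronan synthase, was at 31.7 ± 12.1 CPM (SD, n = 3) there and at 3.66 ± 2.37 CPM in fibroblast-like cells outside cluster 6. Cluster 7 was led by RETN, MMP8 and MMP7, with RETN at 829 ± 448 CPM, and cluster 15 by CCL17, a chemokine of dendritic cells, at 632 ± 369 CPM. Cluster 34, led by SOX18, a factor of vessel lining cells, and LYPD2, held 73, 1 and 0 cells.

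Alk in fibroblast-like cells was weighed against mixed droplets and free RNA. If epithelial-like cells of cluster 21 had been caught in the droplets of cluster 6, Krt8 and EPCAM would stand in the same ratio between the clusters as Alk. The highest of their ratios over the animals was 0.0985, while the lowest Alk ratio was 0.574, which argues against cluster 21 as the source. Both values are from replicate 2, where cluster 21 held 14 cells and 10 Alk UMIs. Clusters 22 and 26, with more Alk, were not tested as sources. Free RNA would give Alk at like levels to all fibroblast-like cells of an animal, yet the Alk-high ones had 5.54 to 14.8 times the level of the others. Alk took no part in the clustering, and the other animals alone picked cluster 6 and neither of the other fibroblast-like clusters for each animal. Alk of the cells themselves, whether edited or native to such stroma, stays open as a hypothesis, since uninfected lung was not used here.

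The bone-type cells of replicate 2 were weighed against bone taken along at dissection. Bone carried along stays open for clusters 22 and 25. Alk was at 48.2 CPM in cluster 22 and 1.10 CPM in the osteoclast-type cluster 25. In cluster 22 it was at 40.6, 48.7 and 44.8 CPM in replicates 1, 2 and 3, from 11, 224 and 10 cells. Bone without the edit was not measured here, so whether the Alk of cluster 22 is native or comes from edited cells cannot be told. No biological explanation was tested.

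The low shares of neutrophil-like and B-like cells in replicate 3 were weighed against the higher lowest UMI total of its barcodes. With a common UMI minimum the neutrophil-like share was 1.90% in replicate 3 and 2.38% and 0.870% in replicates 1 and 2, so the values this explanation needs are there and it could account for the difference. The B-like share was 0.901% against 2.31% and 3.84%, so the minimum is not the whole cause for B-like cells. A difference between animals was not tested.

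Splits of the 6 summed libraries into 3 against 3 number 10, too few for a share under 0.05. The real split gave 110 list genes for epithelial-like, 102 for monocyte or macrophage-like, 142 for T-like and 111 for Alk-high fibroblast-like cells, each with 1 of 10 splits as large, itself, and a highest other of 0. Every other split left the difference between the classes in the residual error, which hides calls. The 0 therefore lends the calls no support. For cells with an Alk UMI the real split gave 0 genes, all 10 splits gave as many, and the highest other gave 15. Of the 10 splits 4, the real one included, part the pair of libraries of every animal. The highest other among these gave 0 in the 4 comparisons of classes and 4 for the Alk UMI, and the highest among those that part 1 pair gave 0 and 15.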
